A study of Homo sapiens with 4 samples.

How the data were processed

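RNA sequencing of 2 human cell lines was analysed. The lines were 293T, an embryonic kidney epithelial line, and A549, a line from a non-small cell lung cancer. Cells of each line had been placed in a magnetic field for 2 h (exposed) or had received no field (control), which gave 4 groups of 3 libraries. Per the labels' protocols, total RNA was isolated with TRIzol and treated with DNase, mRNA was selected on oligo(dT) beads, and cDNA was primed with random hexamers before paired-end sequencing. Transcripts with short or no poly(A) tails are captured poorly by such beads. The strength, frequency and source of the field and the temperature of the cultures were not given in the sources used here, and neither was a sequencing date or batch.

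Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with the genome build GRCh38, and their versions and settings were not given in the sources used here. The values deposited by the authors are FPKM, fragment counts divided by gene length and by the total of the library, for 26348 genes that were each above 0 in at least 1 library. Whether the counting used strand is not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart, and near-identical copies may have exchanged reads. A gene that shares its span with another annotated gene, as small RNA and antisense genes often do, is uncertain to that extent, whether or not this is repeated beside its value. FPKM values share a fixed scale within a library, so a rise of very abundant transcripts lowers all others. The ratios of the deposited FPKM values between libraries were those of whole numbers, and whole counts could be recovered for 100% of the genes within a tolerance of 0.01 counts. The recovered total per library was 37173110 to 38884704 counts, the highest 1.046 times the lowest, so differences in depth between groups were small. These counts were used for the depth, for the share of mitochondrial transcripts and for 1 added alternative. The design fixed before the data were examined called for a test on log FPKM where the table held no count columns, and that test was used.

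Genes with an FPKM of at least 0.5 in at least 3 libraries were kept, which left 13811 genes and removed 12537. No pair of library columns held identical values. The log2(FPKM + 1) values of all 12 libraries were fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group and an intensity trend in the moderated variance, leaving 8 residual degrees of freedom. A fold change on the log2(FPKM + 1) scale understates the change of genes with low values. The contrasts were exposed against control in each line, the difference of these effects between the lines (A549 minus 293T), and the A549 control against the 293T control. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Every adjusted p given for a gene comes from this limma fit unless another setting is named. Ratios given as fold are ratios of mean FPKM. Coordinates and neighbouring genes were taken from the RefSeq annotation of GRCh38.p14, to which 25419 of the listed gene identifiers matched, with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15.

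Before the data were examined, 34 gene lists were fixed for stress responses, cell cycle, signalling, secretion, splicing, mitochondria and line identity. Of their 893 entries 4 had no match. The 32 lists with at least 5 members tested were examined with camera in limma at a preset correlation of 0.01 between genes, with adjustment over these lists, and again with a correlation estimated from the data and with fry. No list was chosen on these libraries. Some genes are on more than 1 list, so the list results are not independent of each other. The genes named were also picked by a rule fixed before the data were examined. For each line it took the 12 largest rises and 12 largest falls among annotated genes past the threshold, with a mean of at least 1 FPKM in the higher group and no overlap between exposed and control libraries. It took 5 genes each way for the difference between the lines and for the controls, RSRP1 always, and 2 to 4 members with the smallest adjusted p from each list described. X-inactivation and Y-linked transcripts were not named, so 1 gene picked by the rule was passed over for the next, and 1 further gene picked by it is not reported here. Genes named outside this rule are marked as such.

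Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean FPKM of at least 1, quantile normalization, rescaling to TPM, a moderated variance without a trend, each line fitted alone, the replicate number as a block, a log2 fold change of at least 1, and leaving out each library in turn. Added after the data were seen were limma-voom on the recovered counts, FPKM rescaled to the same sum without the mitochondrially encoded genes, log2 values centred on the median of each library, and a camera test of 1114 Reactome terms of 15 to 200 tested genes.

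The fit was tested on simulated data, with counts drawn for the real genes from the means, totals and spread of the real libraries and 50 genes changed at each fold in each of 10 draws. With a mean of 13850 genes tested in 293T, 29.8% of genes changed 1.25-fold, 73.8% of those changed 1.5-fold, 88.4% of those changed 2-fold and 95% of those changed 4-fold were recovered. With a mean of 13835 genes tested in A549, the shares were 23.6%, 67%, 86.6% and 94.2%. Genes simulated as unchanged made up 12.6% of the calls in 293T and 10.5% in A549, above the rate the threshold aims at, and 7.9% and 6.4% with limma-voom on the same draws. In these draws the heat shock list, raised 1.5-fold, was called in 10 of 10 draws for each line. Other lists, none of them raised as a list, were called 2 times in 293T and 0 times in A549 over the 10 draws. Each gene was drawn on its own, without correlation between genes, so these list calls do not test the preset correlation. Far fewer genes changed in a draw than were called in the real libraries, so these shares need not hold for the real libraries.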

Results

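The response of 293T and A549 cells to 2 h in a magnetic field was measured by RNA sequencing of poly(A)-selected RNA. Each line was represented by 3 exposed and 3 control libraries, with 37173110 to 38884704 counts per library. Nothing states that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. On the first principal component of the A549 libraries, the exposed libraries lay at 15.7, 18.2 and 9.91 and the controls between -14.93 and -14.01. In 293T the exposed libraries lay at 16.1, 14.7 and 6.51 and the controls between -13.3 and -11.7, so replicate 3 of the exposed group lay nearer to the controls in both lines.

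RSRP1, the arginine and serine rich protein named in the title of the series, was higher in exposed cells of both lines. In A549 it was at 14.7 ± 0.329 FPKM in exposed libraries and 5.37 ± 0.762 FPKM in controls (SD, n = 3 each), a 2.73-fold difference. The log2 fold change was 1.31 (SE 0.10, limma with Benjamini-Hochberg adjustment, adjusted p = 2.36e-06). In 293T it was at 16.1 ± 2.48 FPKM against 8.77 ± 0.429 FPKM, 1.84-fold higher, with a log2 fold change of 0.80 (SE 0.10, adjusted p = 1.10e-04). Each exposed library of a line lay above each of its controls. The rise in A549 exceeded that in 293T by 0.50 on the log2 scale (SE 0.14, adjusted p = 0.0309). That difference was no longer past the threshold in 9 of 12 fits that left out 1 library (adjusted p from 0.00561 to 0.0709) or without the filter on low values (adjusted p = 0.0829). RSRP1 lies on chromosome 1 from 25242249 to 25338254 in GRCh38.p14. RHD, whose gene lies within that span, was listed at 0 in all libraries of exposed 293T and of both A549 groups and averaged 0.00429 ± 0.00372 FPKM in control 293T.

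**Figure D1:**
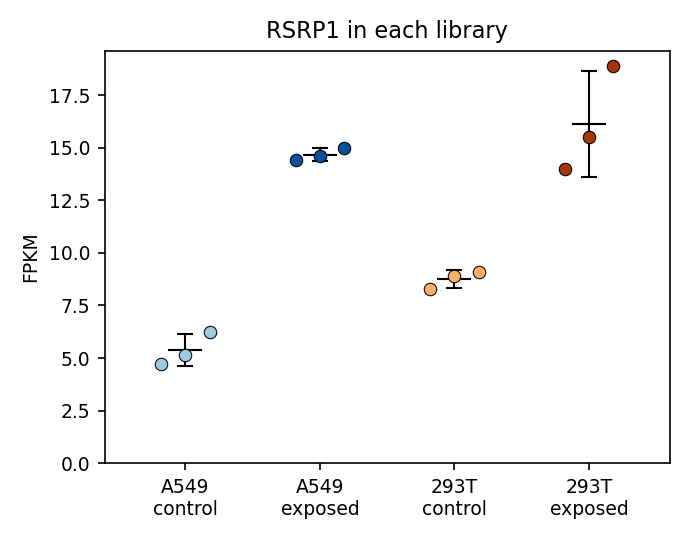
RSRP1 expression in FPKM in each library (points, 3 per group), with the mean (horizontal line) and SD (error bar) of each group. Exposed A549 libraries average 14.7 FPKM and their highest control is at 6.22 FPKM, and exposed 293T libraries average 16.1 FPKM and their highest control is at 9.09 FPKM.

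The first comparison asked which genes differed between exposed and control A549 cells. The largest rises were in inducible chaperones and their partners. HSPA6, an HSP70 gene with little expression in unstressed cells, went from 0.693 ± 0.158 FPKM to 209 ± 192 FPKM (SD, n = 3), with 100, 431 and 95.9 FPKM in the exposed libraries (log2 fold change 6.58, SE 0.64, adjusted p = 1.57e-05). HSPA1B rose 15.7-fold, from 31.2 ± 1.82 to 489 ± 124 FPKM (log2 fold change 3.90, SE 0.19, adjusted p = 4.01e-07), and HSPA1A 11.7-fold, from 49.9 ± 1.30 to 584 ± 144 FPKM. These neighbouring genes are near-identical copies, so the split of reads between them is uncertain. The HSP40 gene DNAJB1 rose by 2.34 on the log2 scale, the HSP70 co-chaperone BAG3 by 2.27 and HSPH1 by 2.08. HERPUD1, a membrane protein of endoplasmic reticulum (ER) associated degradation, rose 7.13-fold (log2 fold change 2.67, SE 0.24). DEDD2 (2.25), the arsenite-inducible ZFAND2A (2.23), DNAJB4 (2.13), the small heat shock protein HSPB8 (2.11) and the YAP target ANKRD1 (2.09) completed the 12 largest rises. DNAJB1, DNAJB4 and HSPB8 each overlap another gene, so their values are uncertain to that extent.

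Among the falls in A549, that of the nuclear non-coding RNA NEAT1 was the largest on the log2(FPKM + 1) scale. NEAT1 went from 41.9 ± 2.69 to 17.5 ± 1.66 FPKM (log2 fold change -1.22, SE 0.06, adjusted p = 5.42e-07). Values per gene do not tell its transcript forms apart. Among the genes picked by rank in A549, by ratio of mean FPKM ZNF296 (3.02-fold), LRFN1 (2.65-fold), SNHG4 (2.56-fold) and CAMKK1 (2.54-fold) fell more than NEAT1 (2.40-fold). NRIP1, a nuclear receptor corepressor, had a log2 fold change of -1.10, the kinase gene CAMKK1 of -1.05, and the calcium channel gene ORAI3 of -0.98. LRFN1 (-0.95) was also among the 12 largest falls. SNHG4 (-1.14), ZNF296 (-0.98), RAI1 (-0.97) and SPSB2 (-0.93) belong there too, but each overlaps another gene (MATR3, GEMIN7, SREBF1 and TPI1), and their values are uncertain. The same holds for GPCPD1 (-0.99), SLFN5 (-0.97) and NEAT1, which overlap a pseudogene, an uncharacterised locus and a microRNA gene. In all, 1837 genes were higher and 3711 lower in exposed A549 cells out of 13811 tested. The balance of directions followed the scaling, with 2695 genes higher and 2525 lower after centring each library on its median, 2400 higher and 2786 lower after quantile normalization, and 1432 higher and 4474 lower when the sum was set without mitochondrial genes. Without replicate 3 of the exposed group 1700 genes were higher and 3612 lower.

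Of 24 heat shock genes tested in A549, 24 rose (24 adjusted over the list alone), with a median log2 fold change of 1.246 (camera adjusted p = 1.49e-28). DNAJA1, which rose by 1.08 (SE 0.06), and HSPA4, which rose by 0.86 (SE 0.05), had small errors for their size. With an estimated correlation the list was at adjusted p = 0.208. Of 25 unfolded protein response genes, 22 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 4.54e-15, and adjusted p = 0.332 with an estimated correlation). DNAJB9, an ER chaperone partner, went from 8.66 ± 0.765 to 26.2 ± 6.58 FPKM (log2 fold change 1.47), DNAJB11 rose by 0.76, and DDIT3, the stress factor CHOP, rose 2.04-fold, though DDIT3 overlaps MARS1. Of 22 genes of the ATF4 amino acid response, 11 rose and 2 fell (11 and 2 adjusted over the list alone), among them CHAC1, a glutathione-degrading enzyme (7.22-fold), and ATF4 itself (log2 fold change 0.40, SE 0.05). That list had a camera adjusted p of 4.39e-04, and adjusted p = 0.376 with an estimated correlation. It shares DDIT3 and ATF4 with the unfolded protein response list.

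**Figure D2:**
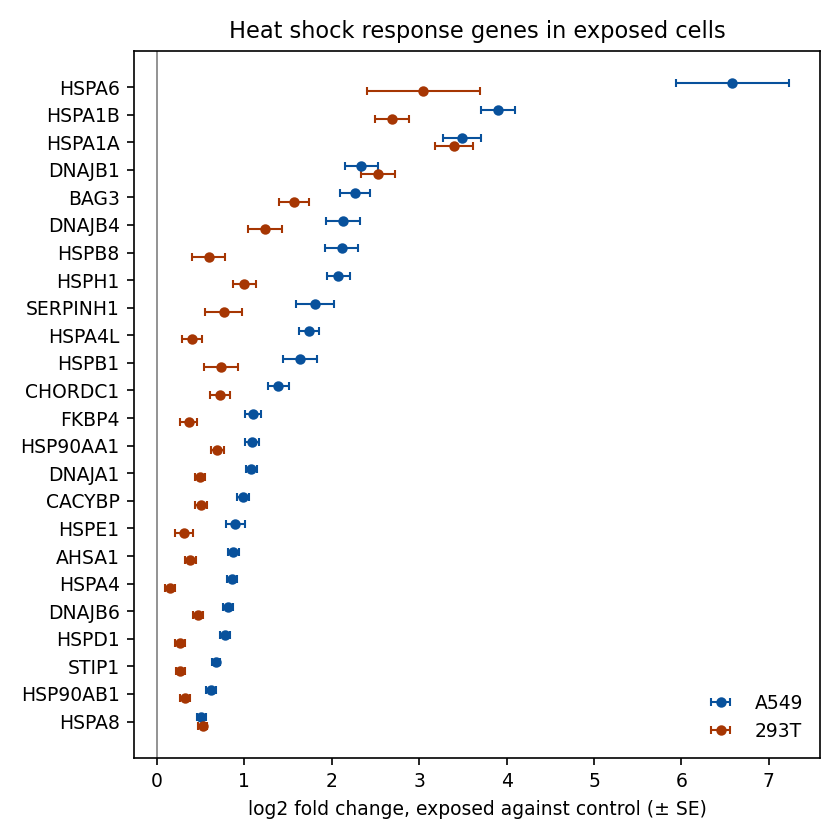
Log2 fold change of FPKM + 1, exposed against control, of the 24 heat shock genes tested, in A549 (blue) and 293T (brown), with 3 libraries per group and error bars of 1 SE from limma. Each of the 24 genes rose in both lines, with medians of 1.246 in A549 and 0.56 in 293T, and the list's camera call was lost with an estimated correlation (adjusted p = 0.208 in A549 and 0.259 in 293T).

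Growth and signalling lists also passed in A549, but they share members. CCN2 is on the YAP and TEAD, immediate early and TGF-beta lists, and CCN1 on the YAP and TEAD and immediate early lists. Of 25 targets of the growth regulators YAP and TEAD, 13 rose and 6 fell (14 and 7 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 7.84e-04, and adjusted p = 0.0863 with an estimated correlation). The matricellular genes CCN1 and CCN2 rose 4.34-fold and 3.15-fold, AJUBA rose by 0.74, and FJX1 had a log2 fold change of -0.59. Of 32 immediate early genes, 12 rose and 3 fell (12 and 4 adjusted over the list alone), including MYC (26.3 ± 0.409 to 45.8 ± 2.50 FPKM) and the phosphatase genes DUSP1 (2.51-fold) and DUSP5 (2.24-fold). Their median of 0.03 became slightly negative when the sum was set without mitochondrial genes, while the camera call stayed (adjusted p = 0.00222, and adjusted p = 0.376 with an estimated correlation). Of 20 TGF-beta targets, 8 rose and 3 fell (8 and 3 adjusted over the list alone), with SMAD6 up by 0.74 and ID3 by 0.54. PMEPA1, on the same list, had a log2 fold change of -0.33. The camera call (adjusted p = 0.0117) was lost with quantile normalization (adjusted p = 0.0711, in a range of 0.00890 to 0.332 by camera over the alternatives) and was at adjusted p = 0.332 with an estimated correlation.

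The title of the series also names secretory signalling. Of 41 secreted cytokines, chemokines and growth factors tested in A549, 13 rose and 6 fell (14 and 6 adjusted over the list alone). GDF15, a stress-induced cytokine, went from 25.1 ± 0.518 to 40.1 ± 1.74 FPKM (log2 fold change 0.66, SE 0.06, adjusted p = 1.08e-05). BMP4 rose 1.86-fold and TGFB2 1.28-fold, while TGFB1 had a log2 fold change of -0.31. The list median was 0.02, slightly negative when the sum was set without mitochondrial genes, and the camera call (adjusted p = 0.0192) was lost with a pseudocount of 0.1 (0.0545), quantile normalization (0.0711) and median centring (0.0659). By camera adjusted p ran from 0.0150 to 0.332 over the alternatives, and adjusted p = 0.332 was that with an estimated correlation. Of 46 genes of the ER to Golgi secretory machinery, 8 rose and 7 fell (7 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0745).

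Of 30 SR splicing factor and CLK kinase genes in A549, the list that holds RSRP1, 8 rose and 9 fell (9 and 11 adjusted over the list alone). CLK1, a kinase that phosphorylates SR proteins, rose 3.66-fold, from 17.6 ± 0.709 to 64.7 ± 9.91 FPKM (log2 fold change 1.81, SE 0.08, adjusted p = 3.70e-07). CLK4 rose 1.97-fold and TRA2A 1.30-fold. The list did not pass by camera (adjusted p = 0.300) but did by fry, which tests against no change (adjusted p = 0.0291), its median of -0.05 and mean of 0.11 differed in sign, and the median became slightly positive after median centring.

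Cell cycle genes split in A549. Of 27 genes of the G1/S transition and DNA replication, 17 fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.0117, and adjusted p = 0.428 with an estimated correlation). The polymerase gene POLE had a log2 fold change of -0.33 and the helicase subunit MCM5 of -0.26, and CHAF1A, which overlaps UBXN6, of -0.31. Of 28 G2/M genes, 10 rose and 5 fell (11 and 5 adjusted over the list alone), among them UBE2C (1.37-fold), CENPA (1.37-fold) and CCNB1 (1.23-fold). Their camera call (adjusted p = 0.0104) was lost with quantile normalization (adjusted p = 0.0549, in a range of 0.00909 to 0.491), did not hold with fry (0.0577) and was at adjusted p = 0.491 with an estimated correlation. Of 20 interferon-stimulated genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone), including IFIT1, which went from 2.50 ± 0.879 to 1.07 ± 0.0822 FPKM, IFIT5 (log2 fold change -0.45), which like IFIT1 overlaps LIPA, and OASL (-0.39). The camera call (adjusted p = 0.0159) was lost with a pseudocount of 0.1 (adjusted p = 0.0545, in a range of 0.00692 to 0.376 by camera) and was at adjusted p = 0.376 with an estimated correlation.

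Of 13 mitochondrially encoded genes in A549, 6 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.14 that was 0 after quantile normalization. ND1, a subunit of respiratory complex I, went from 4919 ± 182 to 3298 ± 162 FPKM (log2 fold change -0.58, SE 0.05), and COX2 had a log2 fold change of -0.25 that was lost with quantile normalization (-0.01, adjusted p = 0.591, in a range of 5.61e-06 to 0.591). The camera call (adjusted p = 0.0374) was lost with quantile normalization (0.747) and median centring (0.0659), and was at adjusted p = 0.502 with an estimated correlation. Of 25 cholesterol synthesis genes, 9 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.00830, and adjusted p = 0.375 with an estimated correlation). Of 24 antioxidant enzyme genes, 8 rose and 4 fell (8 and 4 adjusted over the list alone), a call (adjusted p = 0.0159) lost with quantile normalization (0.348) and at adjusted p = 0.208 with an estimated correlation. Of 38 nuclear oxidative phosphorylation genes, 8 rose and 4 fell (6 and 2 adjusted over the list alone), a call (adjusted p = 0.00237) lost with quantile normalization (0.646) and at adjusted p = 0.332 with an estimated correlation. Of 58 cytosolic ribosomal protein genes, 2 rose (0 adjusted over the list alone). Their camera call (adjusted p = 5.04e-04) turned to lower after quantile normalization (median -0.06, adjusted p = 2.00e-04), was lost when the sum was set without mitochondrial genes (0.105) and with fry (0.108), and was at adjusted p = 0.468 with an estimated correlation. In total 15 of 32 lists passed in A549, 12 toward higher and 3 toward lower values, and with an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, while fry called 22.

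The same comparison in 293T cells, a line that is not from lung, also showed rises of chaperones. HSPA1A rose from 9.29 ± 0.384 to 112 ± 38.1 FPKM (SD, n = 3; log2 fold change 3.39, SE 0.22, adjusted p = 3.50e-06), and its near-identical copy HSPA1B went from 203 ± 5.62 to 1349 ± 369 FPKM (log2 fold change 2.69). HSPA6 was at 26.0, 27.5 and 3.58 FPKM in the exposed libraries and 0.841 ± 0.105 FPKM in controls. Its log2 fold change of 3.05 (adjusted p = 0.00317) was not past the threshold with limma-voom on recovered counts (adjusted p = 0.187, in a range of 1.44e-04 to 0.187). DNAJB1 rose by 2.53, HERPUD1 by 2.28, DNAJB9 by 1.61 and BAG3 by 1.57 on the log2 scale. Genes of other stress pathways stood beside them, with RHOB, a small GTPase, at 157 ± 46.5 against 30.4 ± 0.383 FPKM, the AP-1 factor JUN at 271 ± 54.4 against 59.1 ± 0.965 FPKM, and DDIT4, an inhibitor of mTORC1 signalling, with a log2 fold change of 2.05 (SE 0.14). ATF3, a transcription factor induced by stress, rose 3.02-fold. CD99 had a log2 fold change of 1.98 (adjusted p = 0.0251), but its 293T controls lay at 1.37, 1.05 and 10.7 FPKM, it lies in a region shared by 2 chromosomes, and the call was lost in 6 alternatives (adjusted p from 0.00230 to 0.104), so its value is uncertain.

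NEAT1 also had the largest fall in 293T on the log2(FPKM + 1) scale, from 9.54 ± 0.378 to 3.78 ± 0.130 FPKM (log2 fold change -1.14, adjusted p = 1.93e-06), while by ratio of mean FPKM PRR22 fell more (2.72-fold against 2.53-fold). TFRC, the transferrin receptor, went from 79.7 ± 1.80 to 42.4 ± 2.23 FPKM (log2 fold change -0.90, SE 0.04, adjusted p = 1.12e-07). PRR22 (-1.12), DCAF16 (-0.90), RFXAP (-0.90), RNF126 and CENPB were among the 12 largest falls, and CENPB, a centromere protein, went from 28.3 ± 0.744 to 15.9 ± 2.40 FPKM. SNHG4, ASH1L-AS1, NAA80, TMEM129 and ARMCX5 belong there too and each overlaps another gene, so their values are uncertain, as are those of NEAT1 and TFRC, which overlap small RNA loci. In all, 1897 genes were higher and 3346 lower out of 13811 tested. After quantile normalization 2403 were higher and 2620 lower, after median centring 2271 and 2720, and when the sum was set without mitochondrial genes 1577 and 3781. Without replicate 3 of the exposed group, the one nearest to the controls, 1891 genes were higher and 3518 lower.

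Of 24 heat shock genes tested in 293T, 24 rose (24 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 1.57e-16, and adjusted p = 0.259 with an estimated correlation). HSPA8, the constitutive HSP70, rose from 1138 ± 8.42 to 1641 ± 129 FPKM. Of 25 unfolded protein response genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 7.04e-14, and adjusted p = 0.259 with an estimated correlation). HSPA5, the ER chaperone BiP, went from 173 ± 2.07 to 460 ± 97.2 FPKM (log2 fold change 1.39, SE 0.15, adjusted p = 6.33e-05), and DDIT3 rose by 1.20. Of 22 ATF4 response genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.37 and with CHAC1 and SLC3A2 up by 1.11 and 0.38. That list had a camera adjusted p of 4.10e-08, and adjusted p = 0.259 with an estimated correlation.

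Of 32 immediate early genes in 293T, 11 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 5.07e-04, and adjusted p = 0.303 with an estimated correlation). KLF6 rose by 1.20 and DUSP1 by 1.24, while MYC went from 23.6 ± 0.999 to 15.7 ± 0.464 FPKM. Of 30 SR splicing factor and CLK kinase genes, 10 rose and 6 fell (10 and 8 adjusted over the list alone). CLK1 rose from 20.3 ± 0.140 to 44.4 ± 2.33 FPKM, CLK4 by 0.94 and LUC7L by 0.50 on the log2 scale, and SRSF5 had a log2 fold change of -0.40. The list did not pass by camera (adjusted p = 0.0790) but did by fry (adjusted p = 0.0144), and its median of 0.01 turned to -0.01 when the sum was set without mitochondrial genes. Of 24 p53 targets, 10 rose and 3 fell (11 and 3 adjusted over the list alone). The cell cycle inhibitor CDKN1A was up by 0.74 and POLH, which overlaps GTPBP2, by 0.37. GDF15 was up by 0.55 at low values, from 0.960 to 1.86 FPKM. The camera adjusted p of the p53 list was 0.00854, and adjusted p = 0.259 with an estimated correlation. Activity of p53 itself was not measured. Of 20 TGF-beta targets, 10 rose and 0 fell (10 and 0 adjusted over the list alone), with PMEPA1 up by 0.62, BAMBI by 0.56 and SMAD6 by 0.54 (camera adjusted p = 8.96e-04, and adjusted p = 0.259 with an estimated correlation).

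Of 41 secreted factors in 293T, 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.192), and of 46 genes of the ER to Golgi machinery 7 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.135). Of 17 replication-dependent histone genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with H2BC11 up by 0.70, H2BC5 by 0.53 and H2BC12 by 0.25. The list median was 0.26 (camera adjusted p = 5.07e-04, and adjusted p = 0.180 with an estimated correlation). Most transcripts of this family lack poly(A) tails, and its genes have near-identical copies, so single members are uncertain. Of 24 targets of the oxidant-responsive factor NRF2, 9 rose and 1 fell (9 and 1 adjusted over the list alone), with UGDH up by 0.46 and PRDX1 by 0.19 and SRXN1 at -0.25. Their call (adjusted p = 0.0102) was lost with quantile normalization (0.0712, in a range of 0.00688 to 0.259) and was at adjusted p = 0.259 with an estimated correlation.

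Of 58 cytosolic ribosomal protein genes in 293T, 20 rose and 0 fell (20 and 0 adjusted over the list alone), RPSA by 0.14 and RPL3 by 0.12. Their call (adjusted p = 2.60e-09) was lost and the median of 0.07 turned to -0.01 with quantile normalization (adjusted p = 0.643, against 0.259 with an estimated correlation), under which RPSA and RPL3 were each at 0.01 (adjusted p = 0.603 and 0.734). Of 13 mitochondrially encoded genes, 7 fell and 0 rose (7 and 0 adjusted over the list alone), with ND1 at -0.52 (SE 0.05, adjusted p = 3.01e-05) and COX1 at -0.26, the latter turning to 0.01 with quantile normalization. The call for this list (adjusted p = 0.0339, median -0.18) was lost with quantile normalization (0.453) and median centring (0.0514), and was at adjusted p = 0.447 with an estimated correlation. The lists of antioxidant enzymes (6 of 24 higher, 1 lower; adjusted p = 0.0102), nuclear oxidative phosphorylation genes (8 of 38 higher, 4 lower; adjusted p = 0.0366) and A549 line markers (4 of 20 higher, 1 lower; adjusted p = 0.0356) also passed, each with the same counts adjusted over the list alone. They lost the call with quantile normalization (0.156, 0.643 and 0.0750) and were at adjusted p = 0.180, 0.345 and 0.259 with an estimated correlation. With limma-voom the oxidative phosphorylation and A549 marker lists lost it too (0.0523 and 0.127), and the former also when the sum was set without mitochondrial genes (0.0929) and with fry (0.0968). In total 13 of 32 lists passed in 293T, 12 toward higher and 1 toward lower values. With an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, while fry called 17.

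**Figure D3:**
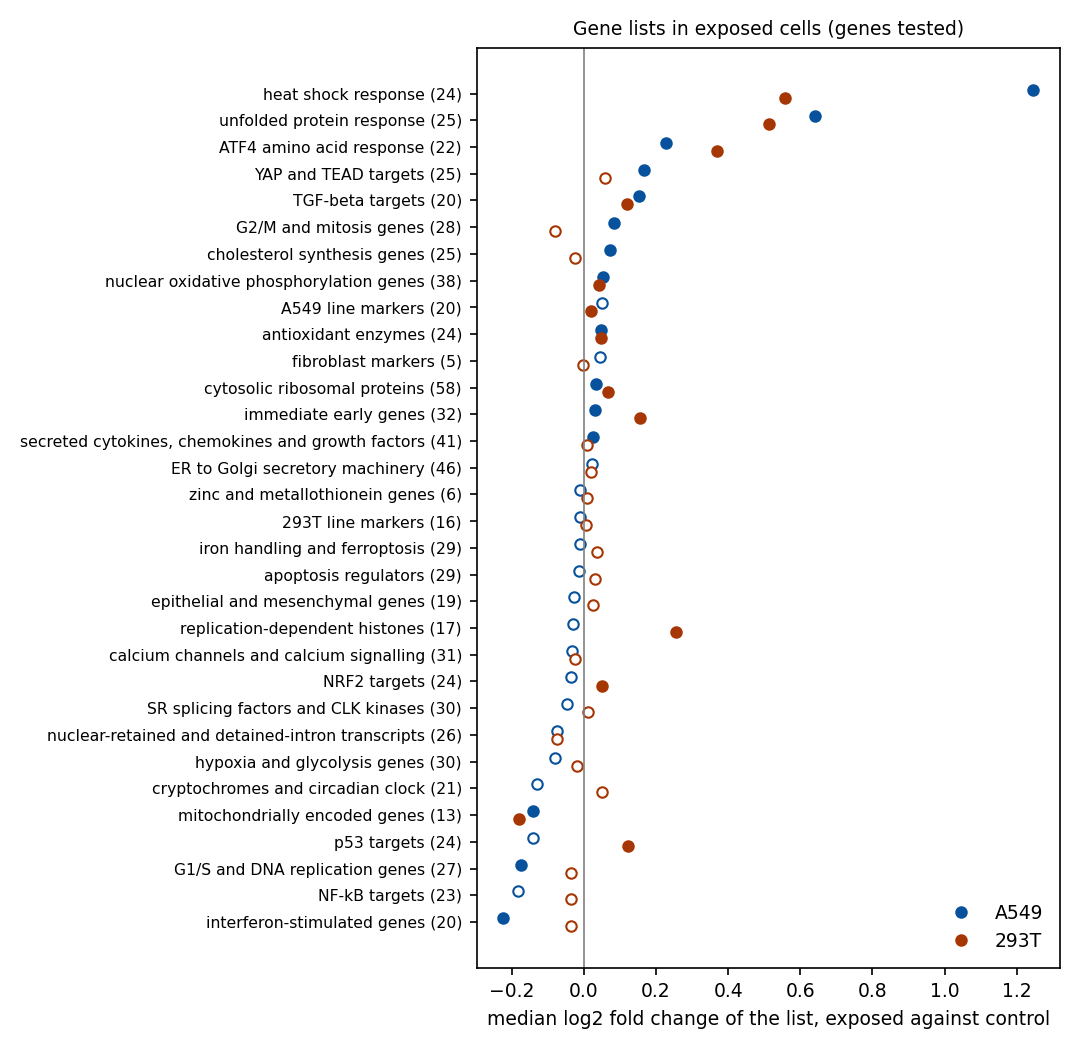
Median log2 fold change, exposed against control, of each of the 32 gene lists tested (number of genes tested in brackets) in A549 (blue) and 293T (brown), with filled points for lists past a camera adjusted p of 0.05 at the preset correlation and open points for the others. The heat shock medians of 1.246 and 0.56 lie farthest from 0 in both lines, no call held with an estimated correlation, and with quantile normalization the cytosolic ribosomal list turned to lower in A549 (median -0.06, adjusted p = 2.00e-04) and lost its call in 293T (-0.01, 0.643), and the mitochondrial calls were lost.

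The third comparison asked where the lines differed in their response. The rise of HSPB8 was larger in A549 by 1.52 on the log2 scale (adjusted p = 0.00411), that of HSPH1 by 1.08 (adjusted p = 0.00383) and that of HSPA1B by 1.21 (adjusted p = 0.0136). Of 24 heat shock genes 18 rose more in A549 and 0 in 293T (21 and 0 adjusted over the list alone; camera adjusted p = 7.68e-14, and adjusted p = 0.415 with an estimated correlation), while 0 of 25 unfolded protein response genes differed by limma (0 adjusted over the list alone). MICB, a stress-induced ligand of an immune receptor on natural killer cells, went from 6.50 ± 0.253 to 27.4 ± 5.72 FPKM in A549 and was at 4.29 ± 0.308 and 4.80 ± 0.288 FPKM in control and exposed 293T (difference 1.77, SE 0.16, adjusted p = 1.05e-04). Its relative MICA, chosen after its values were seen, rose in both lines by 0.25 and 0.24. HSPA1L, next to HSPA1A, rose 6.57-fold in A549, and its difference was 1.68. CCN2 (1.56) and CCN1 (1.54) also responded more in A549. The difference for HSPA6, 3.53 (adjusted p = 0.0259), was lost with limma-voom on recovered counts (adjusted p = 0.551), without the filter (0.0811) and without any 1 of the 293T control libraries (0.0522 to 0.0552), in a range of 0.0204 to 0.551.

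In the other direction, RHOB (difference -1.74, adjusted p = 0.00202), ATF3 (-1.63, adjusted p = 8.94e-04) and DDIT4 (-1.47, adjusted p = 0.00105) rose more in 293T. So did JUN (-1.10, adjusted p = 0.0173), which was at 0.0576 without the filter in a range of 0.00108 to 0.0576. NRIP1 fell in A549 and had a log2 fold change of -0.05 (adjusted p = 0.605) in 293T, a difference of -1.05. MYC rose in A549 and fell in 293T, a difference of 1.34 (SE 0.06, adjusted p = 5.73e-07). TFRC fell in 293T and was at 80.9 ± 1.52 FPKM in exposed and 83.6 ± 0.422 FPKM in control A549 (adjusted p = 0.351), a difference of 0.85. Over all 13811 genes, 761 differed toward A549 and 971 toward 293T, after median centring the split was 967 and 765, and with the replicate number as a block 472 and 575.

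Many genes moved the same way in both lines. The calls of both lines held 873 genes higher in each and 1960 lower in each, against 252.3 and 899.1 for independent lists of these sizes, and 153 genes moved in opposite directions against 954.8. The balance of the shared genes followed the scaling too, with 1241 higher and 1318 lower after median centring, 1160 and 1384 after quantile normalization, and 666 and 2392 when the sum was set without mitochondrial genes. Pearson's r of the log2 fold changes was 0.605 and Spearman's rho 0.562 across genes, which are not independent replicates. NEAT1, HSPA1A, HERPUD1 and DNAJB1 were among the genes with the largest changes in both lines, and the differences between the lines for NEAT1 (-0.08, adjusted p = 0.635), HSPA1A (0.10, adjusted p = 0.875), HERPUD1 (0.39, adjusted p = 0.515) and DNAJB1 (-0.19, adjusted p = 0.701) did not pass the threshold. The lines had separate control libraries.

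**Figure D4:**
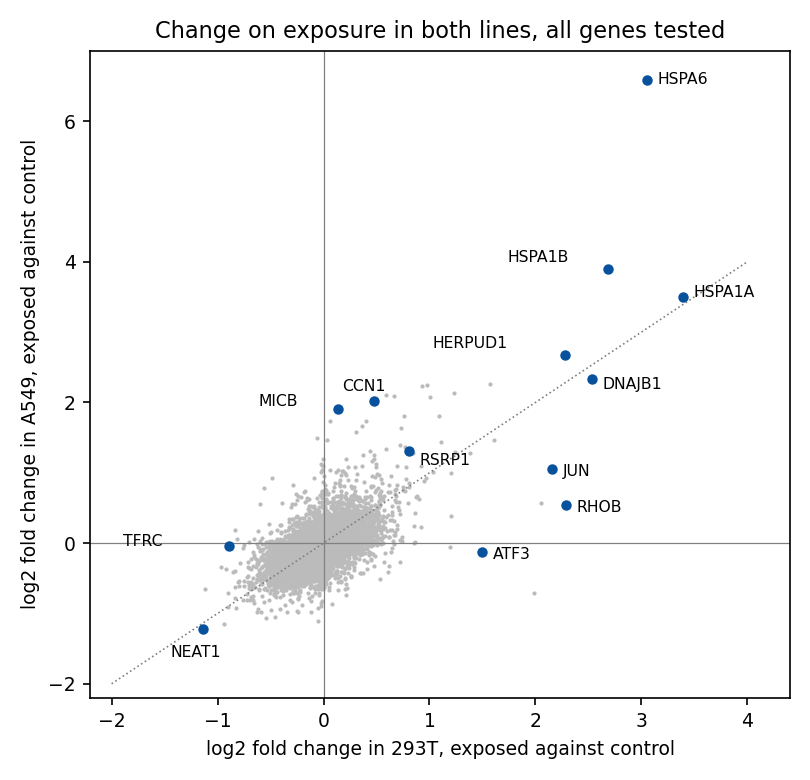
Log2 fold change of FPKM + 1, exposed against control, in 293T (horizontal) and A549 (vertical) for the 13811 genes tested (grey points, mean of 3 libraries per group), with named genes in blue and a dotted line of equal change. HSPA1A lies near the dotted line at 3.39 and 3.49, MICB far above it at 0.13 and 1.90, and RHOB below it at 2.28 and 0.55. The split of reads between HSPA1A and its near-identical copy HSPA1B is uncertain.

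The control libraries of the lines were compared to describe their baseline and to check the labels. ALDH1A1, an aldehyde dehydrogenase abundant in A549, was at 2217 ± 78.9 FPKM in A549 and 3.80 ± 0.147 FPKM in 293T (log2 difference 8.85, SE 0.04, adjusted p = 2.58e-19). S100A6 (9.18), AKR1B10 (8.66), KRT7 (8.53) and KRT81 (8.50) were also far higher in A549, and KRT7 and KRT81 overlap other keratin genes. IRS4, an adaptor of insulin signalling known from embryonic kidney lines, was at 222 ± 1.86 FPKM in 293T and 0.178 ± 0.187 FPKM in A549. PRDX2 (-7.52), AMOT (-7.14), HEY1 (-6.12) and BEX4 (-6.08) were also far lower in A549. Of 20 A549 markers 20 were higher in A549 (20 adjusted over the list alone; camera adjusted p = 3.74e-14, and adjusted p = 0.00406 with an estimated correlation), with KRT18 and AKR1C1 at 4.96 and 5.61. Of 16 markers of 293T, 14 were lower in A549 and 2 higher (14 and 2 adjusted over the list alone; camera adjusted p = 0.00182, and adjusted p = 0.111 with an estimated correlation). NEFM (-5.38), HOXD13 (-4.81) and CKB (-4.78) were lower, and UCHL1 was higher at 2.00.

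Of 24 NRF2 targets, 24 were higher in control A549 (24 adjusted over the list alone), with the transporters ABCC3 and ABCC2 at log2 differences of 6.62 and 6.39 (camera adjusted p = 8.71e-14, and adjusted p = 0.00575 with an estimated correlation). Of 41 secreted factors, 38 were higher and 3 lower in control A549 (38 and 3 adjusted over the list alone; camera adjusted p = 3.74e-14, and adjusted p = 0.00377 with an estimated correlation). RSRP1 was lower in control A549 than in control 293T, with a log2 difference of -0.62 (SE 0.10, adjusted p = 3.99e-05). In all, 4474 genes were higher and 7722 lower in A549. The median over all genes was -0.25, and it moved to -0.15 with quantile normalization and to -0.41 in TPM, so differences of that size carry no direction of their own.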

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

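None of the tests in this part was chosen only after its result was seen: the test of the difference was fixed before the data were examined, and the bound for the regroupings was set after the counts were seen but before any regrouping was run. The effects below are singled out because the response to the field differed between the lines, by a test of the difference itself in limma (A549 effect minus 293T effect, log2 scale, Benjamini-Hochberg adjustment). In all 1732 genes passed this test, and 1047 did with the replicate number as a block. Regrouping the libraries so that exposed and control ones were mixed in both lines gave 82 splits with the real one included, of which 1 reached that number. The highest count in any other split was 0, with 1091 genes at an unadjusted p under 0.05 against 3761 in the real grouping. These regroupings decide nothing, because mixed groups carry the response to the field in their spread, which left a median of 227 genes at an unadjusted p under 0.05 where 691 would be expected with no effect at all. Shared handling of a group is not separated from the field either.

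Most named genes were picked by the size of their change or their adjusted p in these libraries, so their split does not describe all genes. Over all 13811 genes tested, 761 differed toward A549 and 971 the other way, or 967 and 765 after median centring. Among the 43 named genes that passed, 25 had the larger value in A549. Those of chaperones and their partners were HSPA6 (3.53, adjusted p = 0.0259), HSPA1L (1.68, 5.10e-04), HSPB8 (1.52, 0.00411), HSPA1B (1.21, 0.0136), HSPH1 (1.08, 0.00383), HSPA4 (0.71, 2.44e-04) and DNAJA1 (0.59, 0.00135). HSPA6 was not past the threshold in 5 alternatives (adjusted p from 0.0204 to 0.551), and HSPA1B has a near-identical copy. ZFAND2A (1.31, 0.0184) and DEDD2 (1.27, 0.00337) rose with them. Growth-related genes were CCN2 (1.56, 5.10e-04), CCN1 (1.54, 0.00197), ANKRD1 (1.42, 0.00948), MYC (1.34, 5.73e-07), DUSP5 (0.85, 0.00196), BMP4 (0.74, 0.00317), AJUBA (0.57, 0.00159) and TGFB2 (0.24, 0.0270), and mitotic genes were UBE2C (0.42, 8.32e-04), CCNB1 (0.40, 0.00182) and CENPA (0.22, 0.0480). MICB (1.77, 1.05e-04), TFRC (0.85, 6.35e-06), CLK1 (0.72, 0.00215), RSRP1 (0.50, 0.0309, in a range of 0.00561 to 0.0829 over the alternatives) and PRR22 (0.46, 0.0212) completed this set. PRR22 fell in both lines (-0.66 in A549 and -1.12 in 293T), on a scale that understates the change of genes with low values, so its difference is uncertain.

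The other 18 named genes had the larger value in 293T. Stress and early response genes were RHOB (-1.74, adjusted p = 0.00202), ATF3 (-1.63, 8.94e-04), DDIT4 (-1.47, 0.00105), JUN (-1.10, 0.0173, and 0.0576 without the filter, the highest of a range from 0.00108), KLF6 (-0.82, 8.61e-04) and CDKN1A (-0.65, 3.21e-04). Genes that fell more in A549 were NRIP1 (-1.05, 1.11e-04), SLFN5 (-0.85, 5.10e-04), ZNF296 (-0.74, 0.00229), RAI1 (-0.72, 0.00164), CAMKK1 (-0.59, 0.00189), LRFN1 (-0.46, 0.0236), GPCPD1 (-0.39, 0.0180), OASL (-0.38, 0.0158) and the cold-inducible CIRBP (-0.30, 0.0474). PMEPA1 (-0.95, 1.11e-04), UGDH (-0.45, 0.00810) and the histone gene H2BC12 (-0.28, 0.0472) were the remaining genes.

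Of the 32 gene lists, 10 differed between the lines by camera at the preset correlation, 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 12 by fry. The heat shock list had a median difference of 0.63 (adjusted p = 7.68e-14, and adjusted p = 0.415 with an estimated correlation), the YAP and TEAD targets 0.15 (0.00886, and adjusted p = 0.157 with an estimated correlation) and the G2/M genes 0.15 (2.58e-05, and adjusted p = 0.449 with an estimated correlation). The p53 targets were at -0.13 (5.90e-05, and adjusted p = 0.169 with an estimated correlation), the NRF2 targets at -0.12 (0.00657, and adjusted p = 0.415 with an estimated correlation) and the G1/S genes at -0.09 (0.00657, and adjusted p = 0.538 with an estimated correlation). In exposed A549 cells 3 of the 24 p53 targets rose and 10 fell (4 and 12 adjusted over the list alone), with a median of -0.14. That list did not pass there by camera (adjusted p = 0.260) but did by fry, toward lower (adjusted p = 0.00784). The circadian clock genes were at -0.22 (0.00320, and adjusted p = 0.157 with an estimated correlation), and the replication-dependent histones at -0.32 (0.00392, and adjusted p = 0.169 with an estimated correlation). The interferon-stimulated genes were at -0.32 (0.00392, and adjusted p = 0.445 with an estimated correlation), which was -0.04 with limma-voom (adjusted p = 0.632, in a range of 0.00136 to 0.632). The cytosolic ribosomal proteins were at -0.04 (0.0478, and adjusted p = 0.840 with an estimated correlation), a call lost with median centring (0.468) and with fry (0.323), and 0 of these 58 genes passed by limma on their own.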

How the results depend on the processing

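Of the alternatives, limma-voom on recovered counts, the sum without mitochondrial genes and median centring were chosen after seeing the data. With a log2 fold change of at least 1, the counts were 59 higher and 5 lower in A549, 22 and 2 in 293T, 33 for the difference and 3928 for the controls, by construction of that limit. They and their balance depend on the value added before the logarithm and on the scaling, with 125 and 93, 64 and 68, 104 and 5751 for a pseudocount of 0.1, 75 and 25, 38 and 13, 62 and 5476 in TPM, and 175 and 175, 81 and 118, 109 and 5927 with limma-voom. Without replicate 3 of the exposed group the lower ones were 13 in A549 and 6 in 293T, and without control replicate 3 they were 8 in A549. Within a line, residuals of same-numbered exposed and control libraries were not positively correlated (-0.141, -0.074 and -0.043 in A549 and -0.074, 0 and -0.095 in 293T). Whether a number was shared between the lines was not checked, and exposed replicate 3 lay nearer to the controls in both. With the replicate number as a block in each line, 1047 genes passed for the difference, against 1732 without it. Such a fit leaves fewer residual degrees of freedom, which by itself tends to lower the number of calls, and other causes were not tested. The other counts stayed within 1.5 times. The RSRP1 difference was 0.50 without a filter, no longer past the threshold (adjusted p = 0.0829), and 0.41 to 0.61 with 1 library left out (adjusted p from 0.00561 to 0.0709). The number of lists past the threshold was 0 in both lines with an estimated correlation, against 15 in A549 and 13 in 293T, and 7 in 293T with quantile normalization. With quantile normalization COX1 in 293T turned to 0.01 (adjusted p = 0.593), and the cytosolic ribosomal list turned to -0.06 in A549 (adjusted p = 2.00e-04) and -0.01 in 293T (adjusted p = 0.643), the cause not tested.

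With 1 library left out, 1509 to 1893 genes were higher and 2999 to 3830 lower in A549, 1447 to 1952 and 2500 to 3518 in 293T, 1196 to 2017 passed for the difference and 11929 to 12260 for the controls. RSRP1 kept its rise in both lines in each of 23 alternatives, which leave out the limit of a log2 fold change of at least 1 (its 0.80 in 293T lies below that), with adjusted p from 1.57e-07 to 0.00102 in A549 and from 1.24e-05 to 0.00460 in 293T. For 158 values of named genes there were 3605 comparisons with an alternative, of which 3560 kept direction and side of the threshold, 41 were no longer past it, 3 newly passed and 1 turned. For 58 list results there were 464, of which 384 kept both, 78 were lost (51 of them with an estimated correlation) and 2 turned. Alternatives fixed beforehand for deposited counts were not run, since the table used holds no count columns. Genes below the filter were not tested. In the simulated draws most changes of the smallest size were missed, but far fewer genes changed there than were called in the real libraries. With few changed genes the adjusted threshold is stricter, so that share does not carry over to the real libraries. Smaller changes passed there, such as that of PRDX1 in 293T (0.19, against a smallest simulated log2 change of 0.32).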

Other observations

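The tests of 1 scaling factor per library, of histones in A549 and of Reactome terms were chosen only after the results were seen, and FOS and EGR1 after their values were seen. The other tests of explanations were set after the patterns they address had been seen, but before the values they measure were. CIRBP, an RNA-binding protein whose transcript falls when cells are warmed, went from 27.5 ± 1.26 to 15.2 ± 1.51 FPKM in A549 (SD, n = 3; log2 fold change -0.81, adjusted p = 3.44e-06) and had a log2 fold change of -0.51 in 293T (adjusted p = 1.36e-04). RBM3, its cold-inducible relative, fell by 0.35 in A549 (adjusted p = 5.45e-05) and by 0.25 in 293T (adjusted p = 6.79e-04). CIRBP overlaps an antisense gene, so its value is uncertain to that extent. In A549, FOS was at 6.16, 24.0 and 7.55 FPKM in the exposed libraries and between 4.78 and 5.35 FPKM in controls (log2 fold change 0.93, adjusted p = 0.0459). The FOS call was lost in 16 of 23 alternatives (adjusted p from 0.0119 to 0.158), and without exposed replicate 2 the log2 fold change was 0.37 (adjusted p = 0.0551). EGR1 was at 17.4, 53.6 and 19.3 FPKM against 16.4 to 17.2 FPKM (log2 fold change 0.63, adjusted p = 0.114), and was at 0.13 without exposed replicate 2 (adjusted p = 0.325) and 0.91 without exposed replicate 1 (adjusted p = 0.0331), in a range of 0.0331 to 0.325.

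Lists fixed beforehand for clock, calcium and iron genes did not pass by camera for exposed against control in either line. Fry, which tests against no change, called the clock list in both, toward lower in A549 (adjusted p = 9.24e-04) and toward higher in 293T (0.0287). It called the calcium list in A549 (7.97e-04) and the iron list in 293T (0.00366), each toward lower. The NF-kB targets did not pass by camera either (adjusted p = 0.0925 in A549 and 0.548 in 293T). Fry called them toward lower in both (1.11e-04 and 0.0289). Of 23 tested, 3 rose and 13 fell in A549 (3 and 14 adjusted over the list alone). In 293T 0 rose and 6 fell (0 and 6). Of 21 cryptochrome and circadian clock genes, 2 rose and 9 fell in A549 (2 and 9 adjusted over the list alone; camera adjusted p = 0.271) and 5 rose and 1 fell in 293T (5 and 1; camera adjusted p = 0.0903). Of 31 calcium channel and signalling genes, 4 rose and 12 fell in A549 (4 and 12; camera adjusted p = 0.544) and 7 rose and 8 fell in 293T (7 and 8; camera adjusted p = 0.619). Of 29 genes of iron handling and ferroptosis, 5 rose and 8 fell in A549 (6 and 8; camera adjusted p = 0.681) and 6 rose and 8 fell in 293T (6 and 8; camera adjusted p = 0.494). Of 1114 Reactome terms, camera called 47 higher and 8 lower in A549 and 78 higher and 3 lower in 293T. With an estimated correlation camera called 0 in each line, with 38 and 75 at an unadjusted p under 0.05. In the A549 term for activation of chaperone genes by ATF6, 13 of 15 genes rose (adjusted p = 5.04e-07, and adjusted p = 0.956 with an estimated correlation).

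The rise of heat shock genes in both lines could come from warming of the exposed cultures, and its test asked whether CIRBP and RBM3 both fell in both lines. They fell in 4 of 4 values, so warming remains a possible explanation, but other stresses may lower these transcripts too, and neither a culture temperature nor a group warmed without a field is given in the sources used here. Oxidative stress was examined through the NRF2 targets in 293T, whose median was 0.05, with 2 of 4 test genes higher (HMOX1 at 0.21 and GCLM at 0.28), SRXN1 lower and TXNRD1 at -0.02 (adjusted p = 0.733). That test could not tell, HMOX1 and GCLM lost their call in some alternatives (adjusted p from 0.00644 to 0.0733 and from 0.00568 to 0.112), and in A549 3 of the 24 targets rose and 8 fell (median -0.04, camera adjusted p = 0.884, fry adjusted p = 0.0258 toward lower), with HMOX1 at 0.47 (adjusted p = 1.11e-04), SRXN1 lower at -0.38, GCLM at -0.13 (adjusted p = 0.312) and TXNRD1 at -0.05 (adjusted p = 0.204). The 24 targets were already higher in control A549 than in control 293T (median log2 difference 2.681), which may limit further rises. The A549 values therefore do not decide about oxidative stress. No group of this design separates the field from side effects such as warming or oxidative stress, so an effect of the field itself was not tested.

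The fall of mitochondrially encoded transcripts went with a lower share of them in the counts, 7.82 ± 0.135% against 8.83 ± 0.464% in A549 and 4.42 ± 0.0420% against 4.98 ± 0.202% in 293T (SD, n = 3). Quantile normalization brought the median in 293T to -0.01, which cannot tell, because 12 of the 13 genes are among the 50 highest, where that method sets values by rank. The 13 changes spanned 0.58 in 293T, from ND1 to ND3, and 0.67 in A549. A single scaling factor per library is therefore excluded as the whole account, but not as a part of it. With median centring the medians were -0.15 in 293T and -0.09 in A549, and neither list call held by camera (adjusted p = 0.0514 and 0.0659). Poorer capture of transcripts with short or no poly(A) tails was examined through 17 replication-dependent histones. In 293T their median was 0.26, with 6 higher and 0 lower (camera adjusted p = 0.180 with an estimated correlation). The fall that poorer capture predicts was thus not seen there. In A549 their median was -0.03, with 1 higher and 2 lower. Histone transcripts may change for reasons other than capture, and those read after oligo(dT) selection may be the ones with tails. Poorer capture of mitochondrial transcripts therefore stays open in both lines. No biological explanation was tested.

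Regroupings of the 6 libraries of a comparison give 10 splits, too few for a share under 0.05. The real groupings gave 5548 genes in A549, 5243 in 293T and 12196 between the controls, and the highest count in any other split by limma was 0 in each. At an unadjusted p under 0.05 the highest counts in other splits were 866, 1261 and 135 genes. Their medians were 528, 366 and 36, where 691 would be expected with no effect at all. Mixed groups carry the real difference in their spread, which keeps their counts low, so these regroupings decide nothing either.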
